A study of Sus scrofa with 4 samples.

How the data were processed

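Muscle biopsies of pigs (Sus scrofa) of the Hampshire and Mali breeds were analysed, 2 libraries each, grouped by the breed named in the labels. Replicates 1 and 2 were named in accession order. Per the labels' protocols, RNA was isolated with Trizol and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, HISAT2, Bowtie 0.12.2, Picard and Cuffdiff were used, with no role or order given; the genome build and the strand setting are not given in the sources used here.

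The authors deposited 1 table of 30213 rows with an FPKM value per gene and library. The same deposited table holds a mean FPKM per breed, a log2 fold change, a test score, a p-value and a q-value of the authors' own comparison, per the file headers. The fold change column was checked against the means and gives Hampshire over Mali; cells with text stand where the Hampshire mean is 0. FPKM divides by length and library size, so it carries no read depth, and a library in which a few genes take much of the signal lowers all others. In 99.8% of rows the symbol, start and end were those of the Sscrofa11.1 RefSeq table, so coordinates are given in that build.

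One row without a gene name was left out, 26 symbols that a spreadsheet had turned into dates were restored from the gene ID, and rows of a symbol (102 symbols had more than 1) were summed. Genes with at least 1 FPKM in at least 2 libraries were kept. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, Hampshire minus Mali, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The fit had 2 residual and 5.24 prior degrees of freedom.

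Of 35 gene lists fixed before the data were examined, the 33 with at least 3 measured members were tested with camera at a preset correlation of 0.01. The liver-secreted list (2 measured members, median log2 difference 0.51) and the sex-linked list (1 member, EIF1AY, -0.36) were not tested. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run beside it. Newer symbols of 18 list members were matched to the symbols in the file after it was seen.

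Genes were named by a rule fixed before the data were examined. It took 8 genes per direction with a named symbol, at least 5 FPKM in the higher breed and no overlap between breeds, by fold change if adjusted p passed and otherwise by lowest unadjusted p; since no gene passed, all 16 came from the second part. It also took up to 4 members of each described list by lowest unadjusted p, and 12 fixed genes of muscle growth and meat quality.

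The test was checked on simulated data made from the 10075 genes of this comparison, with 50 genes changed at each of 4 sizes. Limma recovered 4% of genes changed by 1 on the log2 scale, 24% at 2, 78% at 3 and 86% at 4, with 3 false among 99 calls. Those data held no replicate block, so they are simpler than the real libraries. With a simulated replicate block, and the block as a term in the fit, 4%, 68%, 92% and 100% were recovered at these sizes. That fit had 5 false among 137 calls. Camera with the preset correlation called 20 of 20 lists of 30 genes shifted by 1 and 0 of 100 unshifted lists. With an estimated correlation it called 0 of the 20 lists shifted by 1, 0 of 20 shifted by 2, 16 of 20 shifted by 3 and 0 of 100 unshifted. Fry called 15 of 20 lists shifted by 1 and 1 of 100 unshifted. Simulated genes were independent, which real list members are not.

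The alternatives were other pseudocounts, filters, scalings, limma settings, the row with the highest mean per symbol, each library left out in turn, and a replicate block by title suffix. Leaving out a library leaves 1 in that breed, whose spread is assumed to be that of the other. Count tests were not run because whole reads could not be recovered. Figures were drawn with matplotlib 3.10.9.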

Results

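Gene expression was measured by RNA sequencing of muscle biopsies from pigs of the Hampshire and Mali breeds, with 2 libraries per breed and 4 in all. The labels describe the breeds as differing in muscularity, and the comparison asks which genes differ between their muscles. The values were FPKM, fragments scaled to gene length and library size, for 29692 gene symbols, of which 10075 reached 1 FPKM in at least 2 libraries and were tested. Read totals are unknown, because the table holds no counts. The FPKM summed to 988614 and 756253 in Hampshire replicates 1 and 2 and to 516463 and 894809 in Mali replicates 1 and 2, and genes of the mitochondrial genome took 42.5%, 21.3%, 19.4% and 17.1% of these sums. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples.

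Insulin-like growth factor 2 (IGF2), a growth factor for muscle, was at 197 ± 87.1 FPKM in Hampshire and 18.1 ± 11.7 in Mali (SD, n = 2 each), a log2 difference of 3.45 with a standard error of 0.62. Cardiac alpha-actin (ACTC1), an actin of developing and regenerating skeletal muscle, was at 138 ± 39.9 FPKM in Hampshire and 16.3 ± 5.64 in Mali. In the other direction, ANKRD1, a stress-responsive ankyrin repeat protein of striated muscle, was at 9.54 ± 6.74 FPKM in Hampshire and 116 ± 47.8 in Mali. The muscle ubiquitin ligase atrogin-1 (FBXO32) was at 8.11 ± 3.96 FPKM in Hampshire and 95.0 ± 70.1 in Mali. Both libraries of one breed lay above both of the other for all 4 of these genes.

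Without a term for library pairs, none of these single-gene differences passed the test. With limma and Benjamini-Hochberg adjustment, 0 of the 10075 genes had an adjusted p under 0.05. An unadjusted p under 0.05 was found for 714 genes, where chance alone gives about 504. The same test on the libraries split by title suffix instead of breed gave 772 such genes. The crossed split, which groups libraries that share neither breed nor suffix, gave 167. Such counts thus ranged widely around 504, and 714 against 504 is no evidence of a breed difference. The adjusted p was 0.417 for IGF2, ACTC1, ANKRD1 and FBXO32. With no gene called, the split of changed genes by direction is undefined. Of the 714 genes, 432 (60.5%) were higher in Hampshire. Other scalings gave other sets of genes at unadjusted p under 0.05. The share higher in Hampshire was 23.4% of 734 genes when FPKM were rescaled to a common sum per library. It was 73.1% of 718 genes with median-of-ratios size factors. The median log2 difference of all genes was -0.12 as deposited, -0.41 after the rescaling to a common sum and -0.01 with size factors.

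The libraries also fell into pairs that cross the breeds. The ratio of low FPKM values took 1 sharp value between Hampshire replicate 1 and Mali replicate 1, with 24.2% of low rows in a single bin, and between Hampshire replicate 2 and Mali replicate 2, with 15.7%; the other library combinations had at most 5.55%. With the pair as a term in the fit, limma called 261 genes at adjusted p under 0.05, 178 higher and 83 lower in Hampshire. That fit had 1 residual and 27.4 prior degrees of freedom, so the calls rest mostly on variance borrowed from other genes. With median-of-ratios size factors added, 57 genes were called, 40 higher and 17 lower. Later gene counts with the pair term come from the fit that called 261. The 16 genes picked from these libraries by lowest unadjusted p and no overlap, and so likely to pass, all passed in that fit, with adjusted p of 3.37e-04 for IGF2, 8.40e-04 for ACTC1, 2.10e-04 for ANKRD1, 1.99e-04 for FBXO32 and at most 0.0112. IGF2 was higher in Hampshire by 3.65 within the first pair and by 3.24 within the second on the log2 scale. Across genes, which are not independent replicates, the breed differences of the pairs correlated with r = 0.217. Library correlations across genes (Pearson) ranged from 0.894 to 0.938, with the highest value between the Hampshire libraries. The Mali libraries correlated at 0.916, and each Hampshire library and its paired Mali library at 0.930 and 0.936. By rank (Spearman), the highest value was 0.900, between Hampshire replicate 1 and Mali replicate 1, against 0.895 between the Hampshire libraries. The first principal component (43.1% of the variance) separated replicates 1 from replicates 2, and the second (35.7%) separated the breeds.

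Of the named genes higher in Hampshire, KCNE5, a potassium channel subunit gene on chromosome X (89741187 to 89742732, Sscrofa11.1), was at 8.27 ± 2.84 FPKM against 0.309 ± 0.292 in Mali. SERHL2, a serine hydrolase-like gene, was at 23.9 ± 1.04 against 3.31 ± 0.260 FPKM. STAC, which encodes an adaptor protein, was at 6.69 ± 0.514 against 0.909 ± 0.140 FPKM. CISH, an inhibitor of cytokine and growth hormone receptor signalling, was at 42.1 ± 18.8 against 6.45 ± 0.591 FPKM. GM2A and C1QTNF3 were at 7.25 ± 1.76 and 6.48 ± 1.55 FPKM in Hampshire and at 1.07 ± 0.131 and 0.682 ± 0.607 in Mali. IGF2 lies on chromosome 2 (1469183 to 1496417), ACTC1 on chromosome 1 (136281119 to 136286551), ANKRD1 on chromosome 14 (102603777 to 102612857) and FBXO32 on chromosome 4 (15895875 to 15925929).

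Of the named genes lower in Hampshire, AP1S2, an adaptor subunit of clathrin-coated vesicles, was at 3.57 ± 0.578 FPKM against 18.3 ± 0.142 in Mali. LIMK1, a kinase acting on the actin regulator cofilin, was at 7.46 and 3.47 against 32.2 and 27.7 FPKM. HTATIP2, ZFAND2A, MCUB and SLC43A2 were at 4.03, 1.29, 1.18 and 4.04 FPKM in Hampshire and at 19.7, 10.6, 5.88 and 15.4 FPKM in Mali. None of these 12 further genes passed adjustment without the pair term, with adjusted p of 0.332 for KCNE5 and 0.417 for the others.

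**Figure D1:**
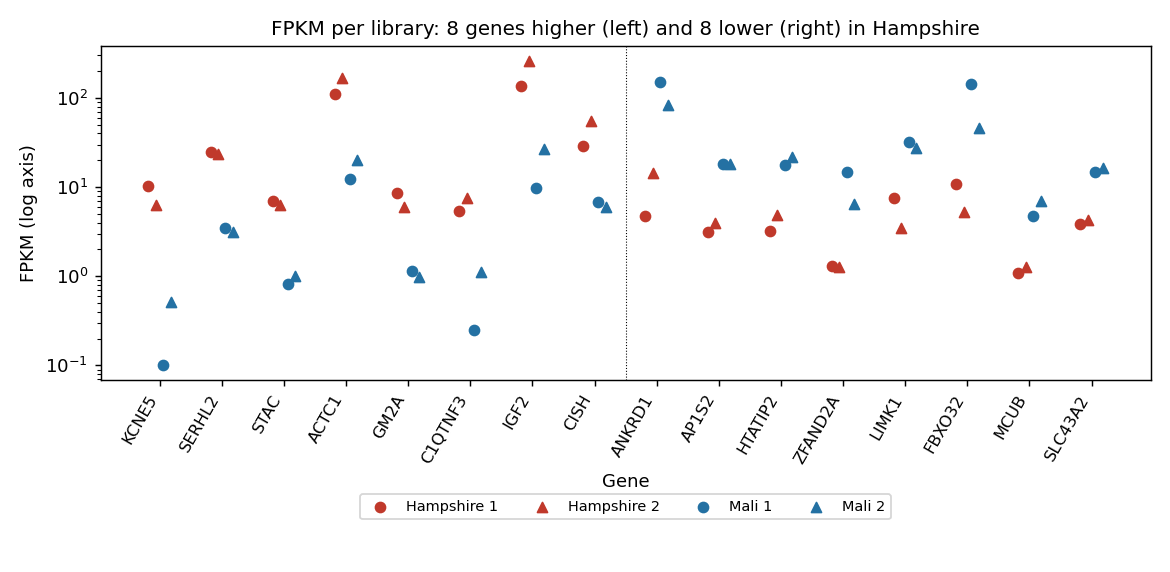
FPKM of 16 genes in each of the 4 libraries on a log axis, with Hampshire in red and Mali in blue and with circles and triangles for replicates 1 and 2. The libraries of the breeds do not overlap for any of the 16, and IGF2 lies at 135 and 259 FPKM in Hampshire and at 9.88 and 26.4 in Mali.

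Besides IGF2, none of the fixed genes of muscle growth and meat quality passed adjustment, with or without the pair term. Myostatin (MSTN), a negative regulator of muscle growth, was at 15.4 ± 1.74 FPKM in Hampshire and 13.2 ± 1.88 in Mali, a log2 difference of 0.21 with a standard error of 0.39 and adjusted p = 0.969 in limma, which turned to -0.12 after rescaling to a common sum. Myogenin (MYOG) was at 24.6 ± 4.55 and 22.6 ± 3.27 FPKM, with a log2 difference of 0.11 that turned to -0.22 under the same rescaling. MYOD1, another myogenic transcription factor, was at 16.7 and 24.7 FPKM in the Hampshire libraries and at 15.7 and 6.51 in the Mali libraries. PRKAG3, a muscle subunit of the AMP-activated kinase, was at 12.6 ± 5.69 FPKM in Hampshire and 36.1 ± 18.2 in Mali, with no overlap between the breeds, and the calcium release channel RYR1 at 354 ± 77.4 and 459 ± 124 FPKM. Of the myosin heavy chains, MYH7 was at 443 ± 2.96 and 312 ± 229 FPKM, MYH2 at 436 ± 184 and 223 ± 201, MYH1 at 2636 ± 1743 and 1233 ± 104, and MYH4 at 3003 ± 3648 and 3797 ± 3124. MYH1, MYH2 and MYH4 are neighbouring paralogs on chromosome 12, and how reads shared between them were assigned is not given in the sources used here, so their values are uncertain. The adipocyte genes ADIPOQ and FABP4 were at 23.4 ± 30.6 and 172 ± 144 FPKM in Hampshire and at 5.08 ± 3.91 and 89.6 ± 25.8 in Mali.

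Interferon-stimulated genes rose as a group in Hampshire. Of the 29 measured members, 27 had both Hampshire libraries above both Mali libraries, where 13.0% of all tested genes did and chance gives 16.7%. All 29 had a positive log2 difference. Their median log2 difference was 1.59, 2.25 within the first pair and 0.96 within the second, and the set passed camera with adjusted p = 2.87e-24; with an estimated correlation the adjusted p was 0.551. IFI6 was at 181 and 106 FPKM in Hampshire and 36.4 and 29.6 in Mali, BST2 at 67.4 and 26.7 against 13.4 and 8.95, and STAT2, a transcription factor of the interferon response, at 8.08 and 5.13 against 2.30 and 1.91. The median was 0.81 without Hampshire replicate 1 and 2.43 without Hampshire replicate 2. Adjusted over the list alone, 14 of the 29 genes passed. Over all genes 0 passed without the pair term and 18 with it.

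Collagen and matrix genes rose as a group in Hampshire, with 32 of 33 measured members positive and 19 separated by breed. The median log2 difference was 1.31, 0.81 in the first pair and 1.82 in the second (camera adjusted p = 3.62e-18; adjusted p = 0.551 with an estimated correlation). Type III collagen (COL3A1) was at 191 and 722 FPKM in Hampshire and 15.6 and 73.6 in Mali. Type I collagen (COL1A1) was at 32.9 and 127 against 8.34 and 14.1 FPKM, and SPARC, a collagen-binding matrix protein, at 259 and 411 against 90.7 and 68.7 FPKM. Fibroblast markers had 16 of 17 positive, 4 separated by breed and a median of 0.88 (camera adjusted p = 3.67e-06, or 0.619 with an estimated correlation). Tendon and cartilage genes had 5 of 5 positive, 3 separated by breed and a median of 1.03 (camera adjusted p = 3.70e-04, or 0.594 with an estimated correlation). The lists are not independent, as the matrix list shares DCN and LUM with the fibroblast list and FMOD and THBS4 with the tendon list. Without Hampshire replicate 2 the matrix median was 0.60 and the fibroblast call was lost, and without Hampshire replicate 1 these medians were 2.27 and 1.504. The fibroblast median was 0.12 without Mali replicate 1, and the tendon median 0.097 with no expression filter. Adjusted over the list alone, 0 genes of these 3 lists passed. Over all genes 0 passed without the pair term, and 12 matrix, 4 fibroblast and 2 tendon genes with it.

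Proteasome genes fell as a group in Hampshire. Of the 31 subunits, 28 were separated by breed, where 23.6% of all tested genes were separated as lower in Hampshire. All 31 subunits were lower in Hampshire within both pairs. Their median log2 difference was -1.05, -1.03 in the first pair and -1.08 in the second (camera adjusted p = 9.86e-13; adjusted p = 0.551 with an estimated correlation). PSMB3, a beta subunit of the core, was at 39.7 and 24.7 FPKM in Hampshire and 93.2 and 104 in Mali, and PSMD2 at 50.4 and 41.6 against 181 and 123 FPKM. Muscle atrophy, calpain and autophagy genes fell too, with 27 of 30 negative and a median of -0.68 (adjusted p = 2.86e-05; adjusted p = 0.551 with an estimated correlation). Their median was -1.02 after rescaling to a common sum. Among them, SQSTM1, an autophagy receptor, was at 105 and 65.8 FPKM in Hampshire and 444 and 291 in Mali. Adjusted over the list alone, 0 proteasome genes and 1 gene of the atrophy list passed, and the same numbers passed over all genes with the pair term.

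**Figure D2:**
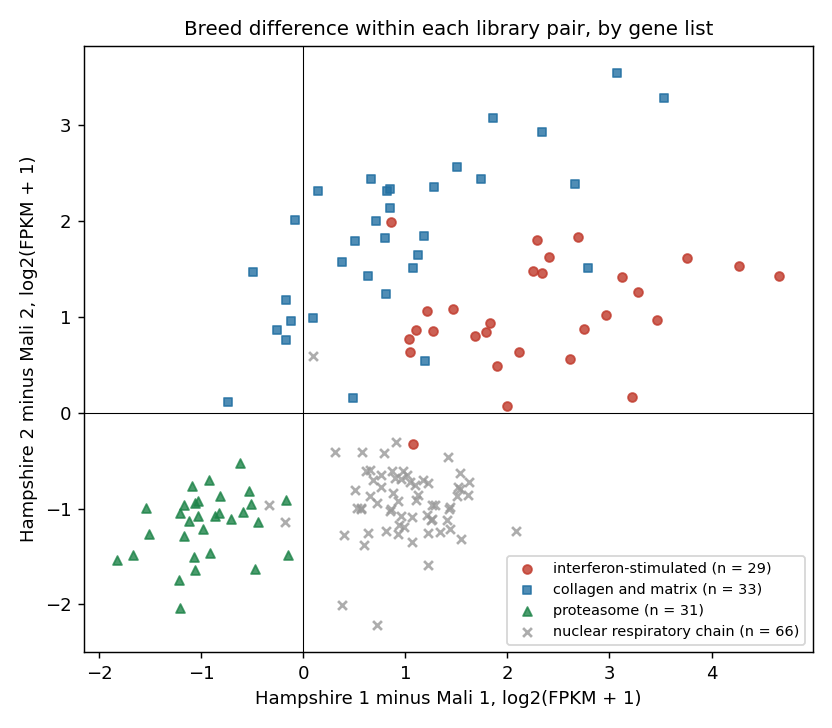
Breed difference in log2(FPKM + 1) within the first library pair (horizontal axis) and the second (vertical axis), 1 point per gene of 4 lists. Interferon, matrix and proteasome genes keep their side of 0 in both pairs for 28 of 29, 26 of 33 and 31 of 31 genes, while respiratory chain genes do so for 3 of 66. Of all tested genes, 55.8% had the same sign in both pairs.

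Antigen presentation genes and immune cell markers rose in Hampshire as well, and the antigen presentation list shares TAP1 with the interferon list. All 18 antigen presentation genes were positive, with a median log2 difference of 0.70 (camera adjusted p = 6.22e-09; adjusted p = 0.551 with an estimated correlation). The class II genes SLA-DQA1 and SLA-DQB1 were at 55.5 and 64.7 FPKM and at 23.9 and 28.5 FPKM in Hampshire, against 14.6 and 12.8 and against 6.67 and 7.56 in Mali. Macrophage markers had a median of 0.90 with 12 of 13 positive (adjusted p = 2.07e-08; adjusted p = 0.551 with an estimated correlation), and LYZ was at 4.96 and 4.14 FPKM against 0.416 and 0.593. Leukocyte markers had a median of 0.50 with 12 of 15 positive (adjusted p = 1.79e-04; adjusted p = 0.594 with an estimated correlation). The leukocyte call was lost without Mali replicate 2 and with a mean of at least 5 FPKM, where the median was 0.058. The macrophage median was 0.47 with no expression filter. After rescaling to a common sum the medians were 0.37 for antigen presentation, 0.62 for macrophage and 0.28 for leukocyte genes. Adjusted over the list alone, 2 antigen presentation, 3 macrophage and 0 leukocyte genes passed, and over all genes with the pair term 2, 2 and 1.

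The regeneration list passed camera as higher in Hampshire (adjusted p = 0.0178, or 0.551 with an estimated correlation), but its members went both ways. Its median log2 difference was 0.89 and its mean 0.29. Of 7 measured members, 4 were higher in Hampshire within both pairs and 3 were lower within both. It was the 1 list that passed fry, with adjusted p = 0.0474. ACTC1, the fusion protein MYMK and the acetylcholine receptor subunit CHRNA1 were higher, with MYMK at 3.71 and 2.71 against 0.435 and 0.468 FPKM, whereas ANKRD1 in the same list was lower. Adjusted over the list alone, 5 of its 7 genes passed, and 4 over all genes with the pair term. Without either Mali library, or after either rescaling to a common sum, the call of this list was lost. It was also lost with a mean of at least 5 FPKM, where the median was -0.94.

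Genes of the mitochondrial genome (median 0.97), red blood cell transcripts (1.34), slow fibre genes (0.33), endothelial (0.37) and smooth muscle genes (0.33), immediate early genes (0.33) and ribosomal protein genes (0.15) passed camera as higher in Hampshire, with adjusted p of 1.50e-04, 0.0219, 0.0252, 0.00329, 0.00329, 0.0179 and 0.0193. With an estimated correlation their adjusted p were 0.663, 0.663, 0.551, 0.663, 0.551, 0.663 and 0.700. Mitochondrial genes had medians of 1.81 in the first pair and -0.06 in the second, and red blood cell transcripts 3.34 and -0.57. Haemoglobin beta (HBB) was at 2525 and 3708 FPKM in Hampshire and at 87.1 and 5469 in Mali, and without Mali replicate 1 the red blood cell list had a median of -0.43. Slow fibre MYL3 was at 755 and 587 against 89.0 and 323 FPKM. ATP8, which overlaps ATP6 in the mitochondrial genome, was at 57793 and 31463 FPKM in Hampshire and 18.5 and 5078 in Mali, and its value is uncertain for that reason. With the library pair as a term, the slow fibre and ribosomal calls were lost (adjusted p = 0.0725 and 0.111). Leaving out 1 library also ended calls of this group. Mitochondrial, red blood cell, slow fibre and ribosomal calls were lost without Hampshire replicate 1. Ribosomal, endothelial and immediate early calls were lost without Hampshire replicate 2. Slow fibre, immediate early, ribosomal and red blood cell calls were lost without Mali replicate 1, and the smooth muscle call without Mali replicate 2. The mitochondrial, slow fibre, immediate early and ribosomal calls were also lost with no expression filter, the mitochondrial and ribosomal calls with quantile normalization, and the immediate early call with a mean of at least 5 FPKM. Without Hampshire replicate 2, where both calls were lost, the endothelial median was -0.13 and the immediate early median -0.078. After rescaling to a common sum the medians were 0.62 for mitochondrial, 1.25 for red blood cell, 0.065 for slow fibre, 0.090 for endothelial, 0.094 for smooth muscle and 0.051 for immediate early genes, and -0.20 for ribosomal protein genes, whose call was lost.

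**Figure D3:**
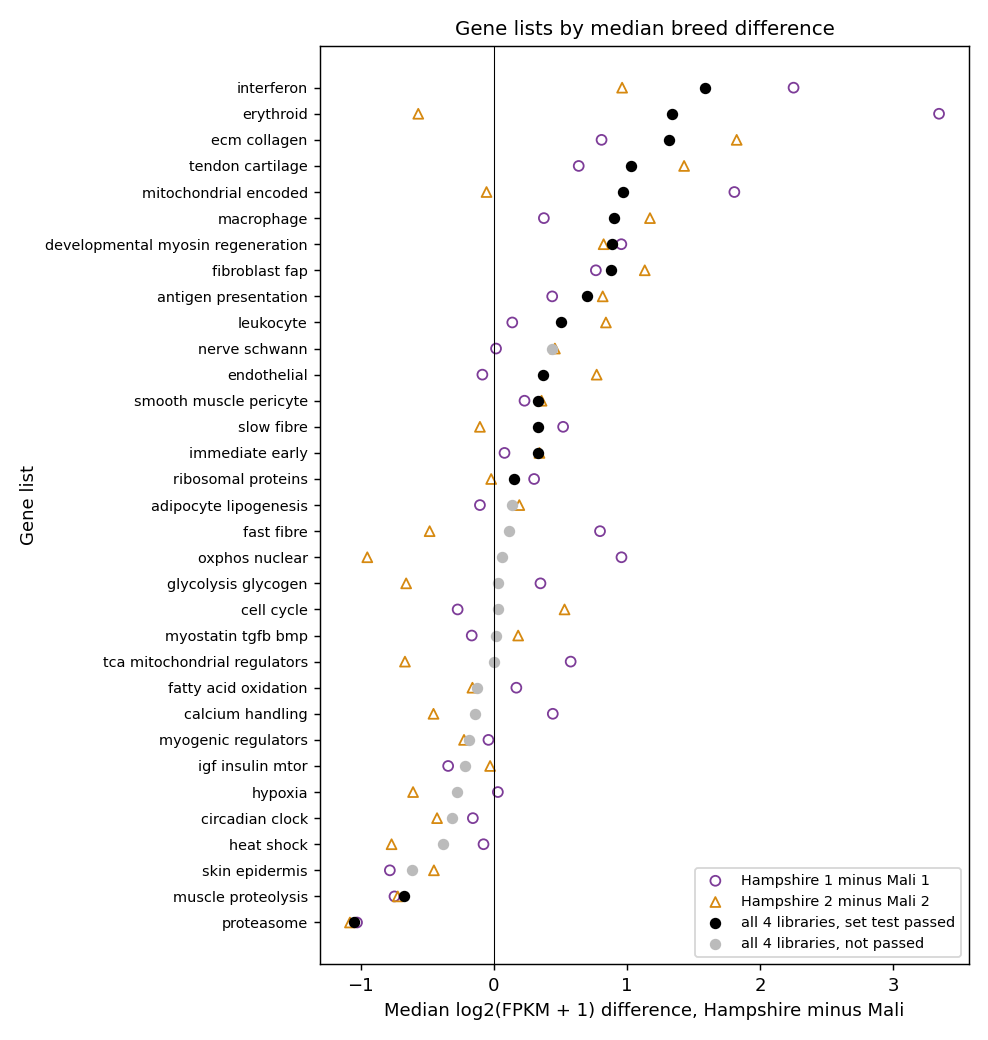
Median breed difference in log2(FPKM + 1) of the 33 tested gene lists, with filled points for all 4 libraries (black where the set test passed) and open circles and triangles for the first and second pair. Interferon (1.59) and matrix genes (1.31) lie to the right of 0 and proteasome genes (-1.05) to the left in both pairs.

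The other 16 tested lists did not pass, though 11 of them did under at least 1 other setting. Heat shock genes passed as lower in Hampshire under 6 settings, which were no expression filter, either rescaling to a common sum, no mean-variance trend, leaving out Hampshire replicate 1, and the pair term with size factors. Skin genes passed as lower under 6, with the pair term (adjusted p = 0.0312), with size factors added to it, with no filter, with the rescaling without mitochondrial genes, and without Hampshire replicate 2 or Mali replicate 1. Nuclear respiratory chain genes passed as higher with quantile normalization, with a mean of at least 5 FPKM and without Mali replicate 2, and as lower without Mali replicate 1. Fast fibre and glycolysis genes also passed as lower without Mali replicate 1 and as higher without Mali replicate 2. Tricarboxylic acid cycle and calcium handling genes passed as higher without Mali replicate 2, adipocyte and myostatin signalling genes without Hampshire replicate 1, fatty acid oxidation and cell cycle genes without Mali replicate 1, and cell cycle genes with no filter as well. Nuclear respiratory chain genes had a median of 0.06, made of 0.96 in the first pair and -0.95 in the second (adjusted p = 0.334), and fast fibre genes a median of 0.12, made of 0.80 and -0.48 (adjusted p = 0.329). Glycolysis genes had medians of 0.35 and -0.66 in the pairs (adjusted p = 0.703). Medians over all libraries were 0.00 for tricarboxylic acid cycle genes, -0.13 for fatty acid oxidation, 0.14 for adipocyte genes, -0.14 for calcium handling, 0.02 for myostatin and TGF-beta signalling, -0.22 for IGF and mTOR signalling, -0.19 for myogenic regulators and 0.03 for the cell cycle. They were -0.38 for heat shock, -0.28 for hypoxia, -0.31 for the clock, 0.43 for nerve and -0.62 for skin genes. Over the settings they ranged over -0.92 to -0.12 for heat shock, -0.61 to 0.036 for hypoxia, -0.64 to -0.15 for the clock, 0.051 to 0.60 for nerve, -1.23 to -0.0032 for skin, -0.32 to 0.13 for myostatin and -0.53 to -0.057 for IGF and mTOR signalling. For myogenic regulators, fatty acid oxidation and calcium handling the set test pointed up while the median lay below 0.

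In the authors' deposited table, 65 genes were marked significant, 43 higher and 22 lower in Hampshire, with a largest q-value of 0.0483. Of these, 48 reached the expression filter used here, 48 had the same direction in limma, 0 had an adjusted p under 0.05 without the pair term, and 45 had one with it. The authors' deposited table marked IGF2 (q-value 0.0433), ACTC1 (0.0179), FBXO32 (0.0179) and COL3A1 (0.0179), and 5 genes each of the interferon and matrix lists and 0 of the proteasome list. Both sets of values come from the same 4 libraries and are not independent.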

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

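The crossed block, the rescaling without mitochondrial genes and the block with size factors were chosen after the data were seen. The labels give no shared replicate numbers beyond a title suffix. With a replicate block by that suffix, limma called 261 genes instead of 0, 57 with median-of-ratios size factors as well and 0 with a crossed block. Deviations from the breed means correlated at 0.275 between libraries of the same suffix. A split of the 4 libraries by suffix called 12 genes, and the crossed split 0. Rescaling FPKM to a common sum gave 72 genes (22 higher, 50 lower) and leaving out the mitochondrial genes first gave 70 (38 higher, 32 lower); both scalings left the prior degrees of freedom far above those of the deposited scale, and the cause was not tested. A mean of at least 5 FPKM and a robust prior gave 1 gene each, LOC110256649, chosen after its values were seen, at 0 and 0.950 FPKM in Hampshire and 39.0 and 29.8 in Mali. Leaving out 1 library gave from 0 to 7 genes, the 7 without Mali replicate 2; other settings gave 0.

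Between 14 and 19 lists passed camera under the 18 settings of values and libraries. Camera with an estimated correlation passed 0 and fry 1, where the cause was not tested beyond the simulation. The estimated correlation was 0.92 for interferon, 0.70 for matrix and 0.45 for proteasome genes, far above the preset 0.01. In fry the adjusted p of these lists were 0.693, 0.693 and 0.393. Interferon, matrix, proteasome, muscle proteolysis, antigen presentation, macrophage and tendon lists, 7 of the 17, passed under all 18, though their medians moved, over 0.81 to 2.43, 0.60 to 2.27, -1.40 to -0.81, -1.02 to -0.54, 0.37 to 0.83, 0.47 to 1.06 and 0.097 to 1.39 in that order. The lowest library correlation was 0.857 with a mean of at least 5 FPKM and 0.867 with a pseudocount of 0.1, against 0.894.

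The camera direction of lists turned as follows, given as median log2 differences; the cause was not tested. Under rescaling to a common sum they were -0.53 for myogenic regulators, -0.31 for glycolysis, -0.34 for the tricarboxylic acid cycle, -0.47 for fatty acid oxidation and -0.48 for calcium handling. With no filter they were -0.030, 0.0062, 0.0072, -0.13 and -0.12 for the same lists and 0.061 for the respiratory chain. With fry, on the main medians, they were -0.19, 0.034, 0.0037, -0.13 and -0.14. With a mean of at least 5 FPKM the regeneration list was at -0.94, adipocyte genes at -0.37 and hypoxia at -0.27. Fast fibre genes were at -0.24 with quantile normalization, and myogenic regulators at -0.19 without a trend and -0.25 without mitochondrial genes. With each library left out in turn, lists whose direction turned at least once had medians of -0.61 to 1.01 for fast fibre, -0.15 to 0.00035 for myogenic regulators, -0.37 to -0.057 for IGF signalling, -0.17 to 0.12 for myostatin signalling, -0.56 to 0.50 for glycolysis, -0.71 to 0.79 for the respiratory chain, -0.37 to 0.24 for the tricarboxylic acid cycle and -0.27 to 0.20 for fatty acid oxidation. The others ranged over -0.17 to 0.36 for adipocyte, -0.50 to 0.21 for calcium handling, -0.35 to 0.45 for cell cycle, -0.078 to 0.58 for immediate early, -0.42 to 0.036 for hypoxia, -0.43 to 2.73 for red blood cell and -0.13 to 0.77 for endothelial genes.

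Of 92 genes named by the rule, 84 kept the sign of their fold change throughout. MSTN (-0.12) and MYOG (-0.22) turned after rescaling to a common sum. With each library left out in turn, genes that turned ranged over -0.070 to 0.29 for MYOG, -0.10 to 1.55 for MYH7, -2.86 to 0.85 for MYH4, -0.96 to 3.09 for ADIPOQ, -0.32 to 1.63 for FABP4, -0.18 to 2.61 for AHSP and -0.84 to 5.12 for HBB. Depth limits are unknown, since the table holds no counts.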

Other observations

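The genes of this paragraph were chosen after their values were seen and were not tested as a group. PHGDH, the first enzyme of serine synthesis, was at 47.4 and 6.03 FPKM in Hampshire and 0.488 and 0.600 in Mali, and PSAT1, the next enzyme, at 20.8 and 3.38 against 0.691 and 0.969. PSPH, the last enzyme, was at 15.6 and 3.41 against 0.315 and 2.85, a log2 difference of 3.66 in the first pair and 0.20 in the second. Neither PHGDH nor PSAT1 passed adjustment over all genes in limma (adjusted p = 0.424 and 0.521), and both did with the library pair as a term (2.43e-05 and 7.78e-04). FKBP5, a glucocorticoid-induced gene, was at 15.6 and 8.34 FPKM in Hampshire and 156 and 47.6 in Mali. DLK1, an imprinted growth gene, was at 3.08 and 5.75 against 0.432 and 0.541 FPKM.

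The tests of fibroblasts, library pairs, a single library, leukocytes, immune cells within each pair and scaling below were chosen only after the results were seen. The bounds for the imprinted, glucocorticoid, NFE2L2 and ATF4 lists were written after those tests had been run but before any of their values was read.

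Collagen and matrix genes were higher in Hampshire. A shift shared by both libraries of a pair cannot produce this, because each pair holds 1 library of each breed and such a shift cancels. The smaller within-pair median of 0.8085 on the log2 scale is therefore no test of it. A shift that fell on the breeds unequally within a pair was not tested. More fibroblasts in the Hampshire samples may contribute: matrix genes exceeded the 15 fibroblast markers outside their list by 0.4898, with a standard error of 0.276, which decides neither way. A difference in growth stage is a candidate explanation. The 9 measured genes of an imprinted growth network list had a median log2 difference of 0.8024 (limma camera, adjusted p = 0.00285 over 4 lists). That support is limited, because the adjusted p was 0.578 with an estimated correlation, the first pair had a median of 0.12 against 1.27 in the second, and the labels used here give no age. The matrix median was also smaller in the first pair (0.81 against 1.82). The imprinted list was not tested against fibroblast content, so it cannot tell growth stage from more fibroblasts. The breed itself remains an untested explanation.

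Interferon-stimulated genes were higher in Hampshire, most in replicate 1, where ISG15 was at 284 FPKM against 16.8 in replicate 2 and 10.2 and 5.61 in Mali (a gene chosen after its values were seen). Hampshire replicate 2 alone had a median interferon value above the Mali mean by 0.8108 on the log2 scale, so the rise was not confined to replicate 1. That value rests on a single Hampshire library, and the list members moved together, with an estimated correlation of 0.92. It therefore cannot tell a breed difference from variation between single libraries. Over both pairs, with a pseudocount of 1, leukocyte markers lay 1.0849 below the interferon genes. That value left out macrophage markers, which had a median of 0.90, and its pseudocount understates low markers. In the first pair, leukocyte and macrophage markers lay 2.3006 below the interferon genes with a pseudocount of 0.1. This argues against more immune cells as the sole cause there. Each pair holds 1 library per breed, so the within-pair values hold for these libraries only. In the second pair the difference was 0.0471 with a standard error of 0.183, so more immune cells may account for the interferon genes there. An infection stays open and was not tested.

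Proteasome genes were higher in Mali. Scaling between libraries is argued against, as the least negative median over 4 scalings was -0.8071. A glucocorticoid response could accompany the pattern, but the list had a median of -0.3809 (limma camera, adjusted p = 0.348) and decided neither way. Its medians were -0.51 in the first pair and -0.15 in the second, with 8 of 12 measured genes negative and 4 positive. The list left out FKBP5, which had a log2 difference of -2.81. NFE2L2 targets, at -0.0879 (limma camera, adjusted p = 0.822), gave no sign of the oxidative stress response and did not exclude it. Whether the animals differed in feeding or handling stays open.

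For serine synthesis, an ATF4 response in Hampshire was the hypothesis, and 15 measured ATF4 targets had a median of -0.1218 and a mean of 0.24 (limma camera pointing up, adjusted p = 0.419). The list left out PHGDH, PSAT1 and PCK2, which had been seen, but holds the serine synthesis gene PSPH, so it is not independent of the pattern. Its medians were 0.42 in the first pair and -0.64 in the second. PSPH and MTHFD2 passed with the pair term (adjusted p = 0.0193 and 0.0346), while ASNS and ATF5 were higher by 4.15 and 3.98 in the first pair and lower in the second. SLC3A2 and CTH were lower in Hampshire in both pairs, with log2 differences of -1.55 and -0.72. Of the 15 members, 6 were positive and 9 negative, so the list leaves the hypothesis open.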
